A study of Chlorocebus aethiops with 3 samples.

How the data were processed

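Heavy polysome RNA of COS-7 cells, a fibroblast-like kidney line of the African green monkey, was compared on 3 Agilent 2-colour expression arrays. On each array the Cy5 channel held RNA of cells transfected with siRNAs against RNA helicase A (RHA), and the Cy3 channel held RNA of cells given scrambled siRNA. Per the labels, the arrays are biological replicates 1 to 3. The dye orientation was the same on all 3 arrays and all lie on 1 slide, so neither dye nor slide could be a term of the model. The probes belong to Agilent design 014850, annotated by the file headers on the human genome, so monkey RNA was measured with probes made for another species.

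Per the file headers, the authors' spot intensity values were extracted with Agilent Feature Extraction 10.9.1.1, and the submitters' processing notes give version 10.9 and name limma without a version. The deposited scanner tables hold median spot and local background intensities, flags per spot, processed signals, and a log10 ratio of Cy5 over Cy3. Checked on the deposited values, that log10 ratio equals that of the processed signals within a tolerance of 1e-04 or is exactly 0, the latter on 31.1% of spots. The authors' series value table holds log2 ratios whose scale, centring and direction are not stated. Set against the scanner values, those log2 ratios followed loess-normalized Cy5 over Cy3 signals without background correction, with Pearson's r of 0.995, 0.994 and 0.994 and slopes of 1.06, 1.07 and 1.05 on replicates 1, 2 and 3. Their medians were 0, 0.01 and 0.01, so they are centred near 0. The positive slopes show that they give knockdown over control. This table was used as an alternative.

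The values reported here were computed from the scanner intensities in R 4.3.3 with limma 3.58.1. The plan named mean spot signals. The tables used here give medians, which took their place. Background was corrected with normexp and an offset of 50 over all spots, and each array was normalized with loess in which control spots had weight 0. No normalization between arrays was applied. Spots with a non-uniformity or population outlier flag in either channel were left out on that array, between 142 and 150 of 43376 probe spots, and no probe spot was saturated. Spots of 1 probe were averaged. A probe was tested when it was well above background on all 3 arrays in at least 1 of the channels, which left 18143 of 41000 probes. An offset of 50 pulls the ratios of dim probes toward 0.

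The log2 ratio of knockdown over control was tested per probe with lmFit and eBayes on an intercept, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Each array gives 1 ratio, so n is 3, and an exact sign-flip test of a single probe cannot go below p = 0.25. The number of arrays limits the precision. Data were simulated with the arrays' own spread per probe and 200 changed probes among 18139. There the probe test found 0% of changes of 0.5, 26.6% of changes of 1 and 68.4% of changes of 2 on the log2 scale. Of its calls, 1.06% were false. In the real data 3332 probes were called, with log2 ratios down to 0.38 in size. The adjustment is stricter when few probes change, so the simulated rates do not describe the test on the real data.

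The scanner files pair each probe with a sequence accession and not with a gene symbol, and no annotation table was used here. RHA alone could be named, since the labels give its human accession, NM_001357. The planned results for JUND and for 34 gene lists, among them the markers of other cell types and compartments, were therefore not computed, and genes were replaced by accessions, each represented by its brightest tested probe. A gene with several accessions counts more than once. The rule for named genes asked for the 10 largest risen and 10 largest fallen genes with a symbol. With no symbols it was reduced to the 2 NM accessions with the largest rise and the 2 with the largest fall among those past the threshold with 1 sign on all 3 arrays. This reduction, the use of median signals and of accessions, and the comparison of probes of an accession were also chosen after the files were seen. Grouping of accessions by their prefix was likewise chosen after the files were seen and tested with camera (preset correlation 0.01, and an estimated one) and Fisher's exact test. The test, the filter and the alternatives were otherwise fixed before the data were examined, except median centring on the tested probes, which was added later. The alternatives changed the background correction, the normalization, the filter, the flags, the variance model, the array weights, the source of the values and the probes per accession, and left out each replicate. Restricting the probes to those matching the monkey genome was not run, since neither probe sequences nor that genome were used here.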

Results

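The arrays measured which RNAs lay in the heavy polysome fractions of sucrose gradients, where mRNAs carrying many ribosomes sediment, after transfection with siRNAs against RNA helicase A (RHA, encoded by DHX9). RHA is a DEAH-box helicase that binds structured RNA and is known to promote translation of selected mRNAs. The series asked how polysome loading changes when RHA is down-regulated. RNA from knockdown cells was set directly against RNA from control cells on 3 arrays, 1 for each biological replicate. The ratios report the amount of an RNA in heavy polysomes relative to the other RNAs there, which moves with the abundance of the RNA as well as with its loading. Total RNA was not analysed here.

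Of the 41000 probes, 37.5%, 38.7% and 50.7% were well above background in the control channel of replicates 1, 2 and 3. In the knockdown channel the shares were 45.5%, 46.2% and 53.1%. The median probe signal was 31, 30 and 38 in Cy3 against local backgrounds of 26, 27 and 27.5, and replicate 3 was the brightest array. Accessions of RefSeq mRNAs, which carry the NM prefix, were measured more often than those of RefSeq non-coding RNAs, which carry the NR prefix. At least 1 probe was tested for 10826 of 18389 NM accessions, or 58.9%, with an exact (Clopper-Pearson) 95% interval of 58.2% to 59.6%. For NR accessions it was 271 of 879, or 30.8%, with an interval of 27.8% to 34.0%. The odds ratio was 3.21 and Fisher's exact test, 2-sided, gave p = 3.48e-60. These intervals cover counting error only, and the probes were designed on human sequence.

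The first question was whether the siRNAs lowered the RHA message in heavy polysomes. The RHA message of the whole cell and the RHA protein were not measured on these arrays. The siRNAs were designed on the human sequence, per the labels, and the cells were from a monkey. The array carries 3 probes for the RHA accession NM_001357, and the files do not place them relative to the siRNA target sites. Probe A_24_P36847 had log2 ratios of -0.12, -0.12 and -0.76 on replicates 1, 2 and 3, a mean of -0.33 ± 0.37 (SD, n = 3), which corresponds to 0.795 times the control level. Probe A_23_P97749 had -0.041, -0.20 and -0.60, a mean of -0.28 ± 0.29 (SD, n = 3), or 0.824 times the control level. Both probes lay below 0 on 3 of 3 arrays, and neither passed the test, with limma adjusted p of 0.210 and 0.217. The 95% intervals of their log2 ratios ran from -0.74 to 0.077 and from -0.63 to 0.072. Without replicate 3 the mean log2 ratio was -0.12 for both probes. Agilent's processed log ratio gave -0.73 and -0.38, with limma adjusted p of 0.0838 and 0.344. The third probe, A_24_P808534, was well above background in 1 of 3 control channels and 0 of 3 knockdown channels and was left out by the main filter. At these dim signals its log2 ratios were -0.29, 0.13 and -0.12, a mean of -0.093 ± 0.21 (SD, n = 3). Its mean ranged from -1.36 with Agilent's processed log ratio to -0.092 with median centring. The sign of both tested probes depended on the normalization: median centring of each array in place of loess gave mean log2 ratios of 0.068 and 0.26, and centring on the median of the tested probes gave -0.25 and -0.055. Over the alternatives tried, the limma adjusted p of these probes ranged from 0.0838 to 0.867. A fall of the RHA message in heavy polysomes was thus not established by these arrays, which cannot tell whether the knockdown worked in the cell. The groups are called knockdown and control after the labels.

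**Figure D1:**
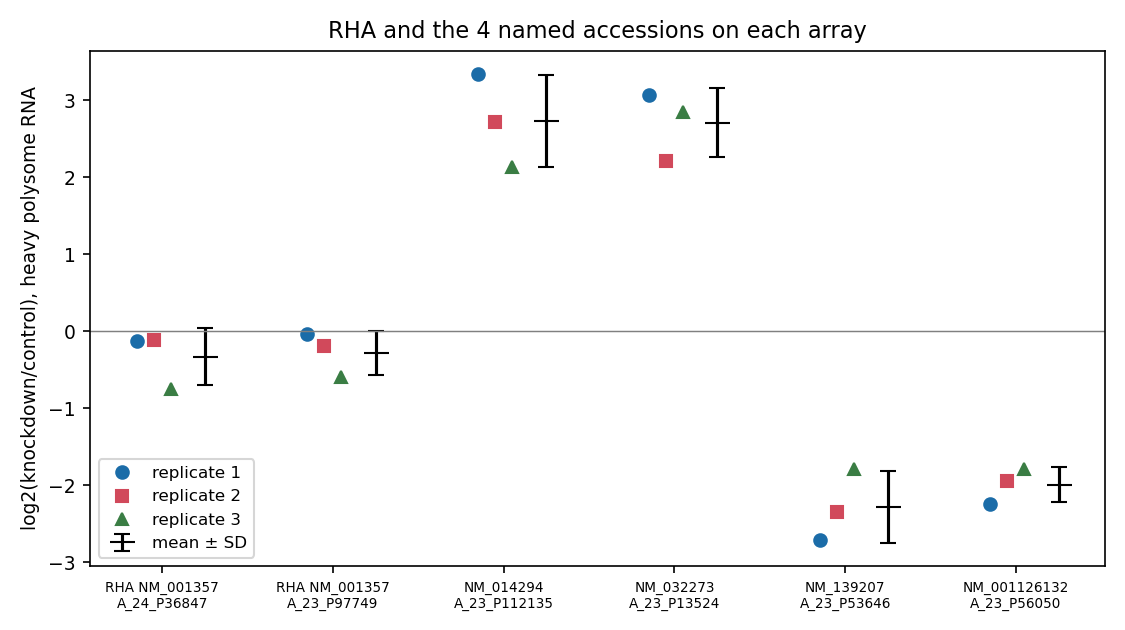
Log2 ratio of knockdown over control in heavy polysome RNA (y axis) for the 2 tested RHA probes and the 4 named accessions (x axis); symbols are the 3 arrays and bars the mean ± SD. The RHA probes had means of -0.33 and -0.28 with replicate 3 lowest, and the named accessions, which were picked for size and for 1 sign on all arrays, had means of 2.73, 2.71, -2.28 and -1.99.

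The main comparison asked which RNAs became more or less abundant in heavy polysomes after knockdown. Of 18143 probes tested, 1763 rose and 1569 fell (limma, adjusted p under the threshold of 0.05), which is 18.4% of the probes. By at least 2-fold, 497 rose and 334 fell. The 2-fold counts depended on the processing, with 1263 risen and 785 fallen probes at a normexp offset of 0, 2344 and 1396 with Agilent's processed log ratio, 2099 and 12 with median centring, and 286 and 204 with no filter on dim probes. The count of all risen probes was between 1066 with no filter and 3001 with an intensity trend in the variance among the loess-normalized alternatives with 3 arrays. Among 14526 accessions, 1439 rose and 1356 fell, and by at least 2-fold 416 rose and 309 fell. The median size of a called probe's log2 ratio was 0.75, and the smallest was 0.38. With median centring in place of loess, 3561 probes rose and 59 fell, so that 98.4% of calls were upward instead of 52.9%. That setting moved the median log2 ratio of the tested probes from 0.018 to 0.30. Directions are given here relative to the loess curve of each array at a probe's own brightness, and not to the array's overall median. Centring on the median of the tested probes, chosen after the data were seen, gave 3127 risen and 1087 fallen probes, or 74.2% upward.

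The RefSeq mRNAs with the largest rise and fall were picked among those past the threshold with 1 sign on all 3 arrays, so their likeness across arrays was fixed by the choice and their ratios may overstate the change. NM_014294, measured by probe A_23_P112135, rose with log2 ratios of 3.34, 2.72 and 2.14, a mean of 2.73 ± 0.60 (SD, n = 3), or 6.64-fold. NM_032273, measured by A_23_P13524, rose with log2 ratios of 3.07, 2.21 and 2.85, a mean of 2.71 ± 0.45 (SD, n = 3), or 6.55-fold. NM_139207, measured by A_23_P53646, fell with log2 ratios of -2.71, -2.35 and -1.79, a mean of -2.28 ± 0.46 (SD, n = 3), which is 0.205 times the control level. NM_001126132, measured by A_23_P56050, fell with log2 ratios of -2.24, -1.94 and -1.79, a mean of -1.99 ± 0.23 (SD, n = 3), or 0.252 times the control level. All 4 had a limma adjusted p of 0.0139 over accessions, and each was well above background in both channels of every array. Each of the 4 accessions is represented by 1 probe on the array. The files do not pair these accessions with gene names. Without replicate 2, the 4 kept their sign with log2 ratios of 2.74, 2.96, -2.25 and -2.02, at a limma adjusted p of 0.117, where their alternatives ranged from 1.16e-09 to 0.117.

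The ratios were alike on the 3 arrays. Across the tested probes, Pearson's r was 0.74 between replicates 1 and 2, 0.64 between 1 and 3, and 0.70 between 2 and 3, with Spearman's rho of 0.69, 0.58 and 0.66. Probes are not independent replicates, and all 3 arrays share the dye orientation. Of 18139 probes with a value on every array, 10589 (58.4%) had 1 sign on all 3, where chance gives 25%. The SD of the log2 ratios was 0.61, 0.48 and 0.43 on replicates 1, 2 and 3. For the 171 tested probes that the design prints as 10 spots, the median SD between spots of an array was 0.077 and that between arrays 0.21 on the log2 scale.

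**Figure D2:**
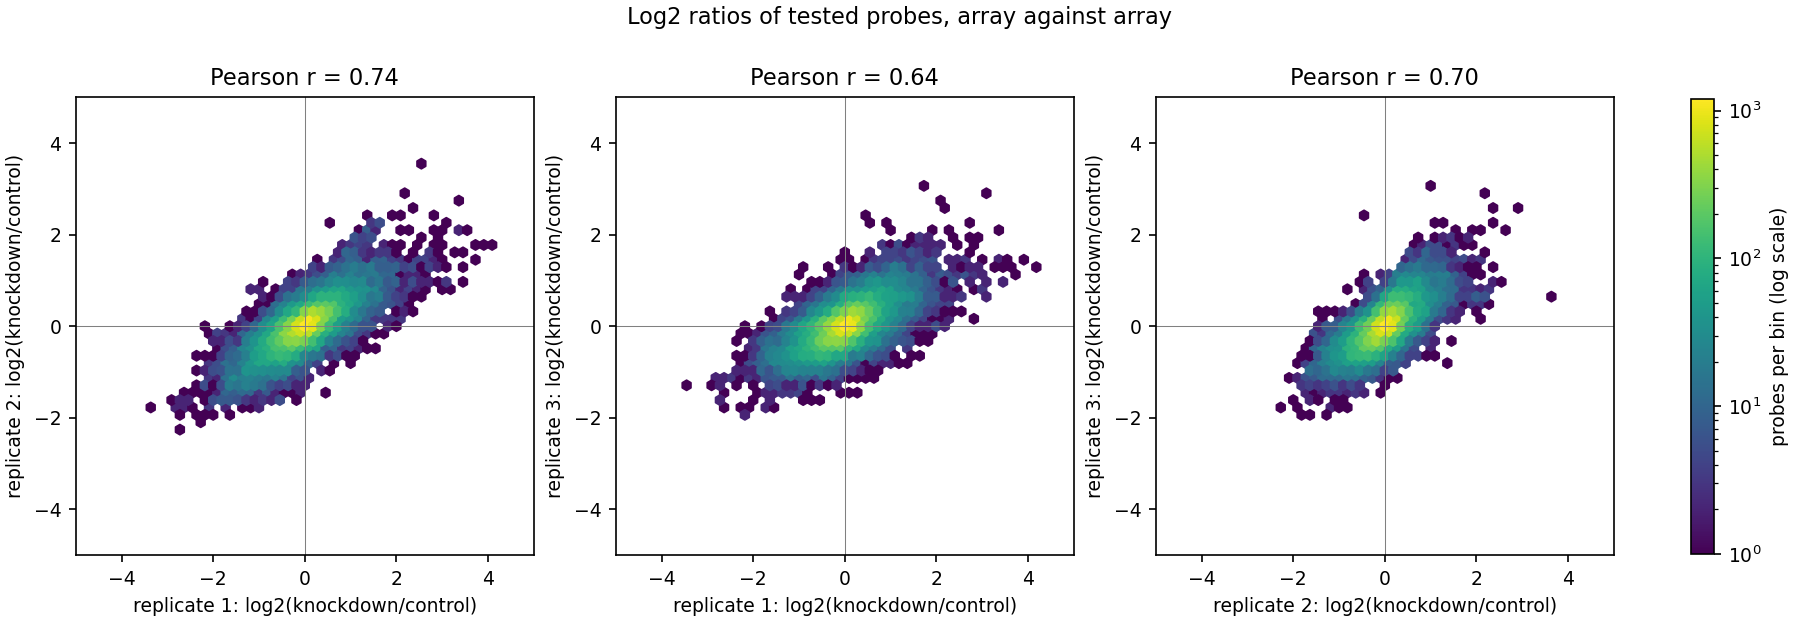
Log2 ratio of knockdown over control of the tested probes on 1 array (x axis) against another (y axis) for the 3 pairs of arrays; colour gives the number of probes per bin on a log scale. Pearson's r was 0.74, 0.64 and 0.70, and the points of replicate 1 spread wider than those of replicate 3.

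Different probes of an RNA gave like ratios. For 2915 accessions with at least 2 tested probes, the 2 brightest were compared. Spearman's rho between their mean log2 ratios was 0.62, with a bootstrap 95% interval of 0.60 to 0.65. Both probes were called for 266 accessions, with the same sign in 265 and opposite signs in 1. At least 1 probe was called for 897 accessions, and in 797 of them both had the same sign.

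**Figure D3:**
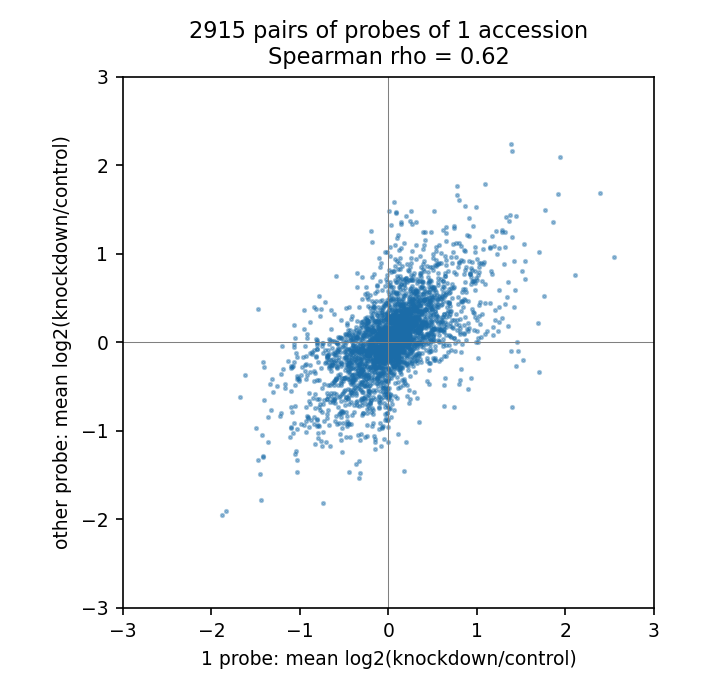
Mean log2 ratio of 1 probe (x axis) against the other probe of the same accession (y axis), 1 point for each of 2915 accessions, in random order within a pair. Points follow the diagonal, with Spearman's rho of 0.62.

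Some probes were well above background in a single channel. A total of 393 probes were well above background in the knockdown channel of all 3 arrays and in the control channel of none. Of these 393 probes, 15 were called risen, where 18.4% of all tested probes were called in either direction. For 8 probes the control channel was well above background on all 3 arrays and the knockdown channel on none, and 1 of them was called fallen. The knockdown channel had the greater number of probes above background on every array, as given above. Knockdown RNA was always in Cy5, with median probe signals of 72.5, 72.5 and 86 against local backgrounds of 58, 57 and 58. A difference in detection between the dyes therefore cannot be told from RNAs present in 1 group only.

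The number of calls changed most when replicate 2 was left out. Limma then called 0 probes, with 2228 above and 2010 below 0 at an unadjusted p under 0.05. Without replicate 1 it called 1280 risen and 1126 fallen probes, and without replicate 3 it called 1502 and 1419. A dye effect shared by all probes of a transcript was not separable from the knockdown, because no array had the dyes swapped.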

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

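The tests of the likeness of the arrays, of the array signs and of the RHA values were chosen after their results were seen. The tests of median centring were chosen after that pattern was seen and before their values were computed.

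Spots outside the main comparison, those of E1A spike-in RNA, gave signals above the negative control spots, and their ratio to the tested probes differed between arrays. The 320 spots of 10 spike-in sequences had median signals of 278.25, 752.25 and 345 in Cy3 and 467.5, 605 and 876.5 in Cy5 on replicates 1, 2 and 3. Negative control spots had 26, 27 and 27 in Cy3 and 60.5, 59 and 59 in Cy5. Before normalization, the median log2 ratio of Cy5 over Cy3 of the spike-ins minus that of the tested probes was -0.27, -1.73 and -0.15. Per the file headers, the slope of observed against expected spike-in log ratios was 0.896, 0.839 and 0.921, with correlations of 0.982, 0.970 and 0.994.

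Possible causes of the likeness of the 3 arrays include the knockdown and a dye effect repeated on every array. The design does not separate these from any other difference between the RNAs of the channels that was repeated on every array. A dye effect of the single probe as the whole cause is argued against by the like ratios of different probes of an accession, with Spearman's rho of 0.624 (bootstrap 95% interval 0.599 to 0.649), where random pairing stayed within 0.065 of 0 in 2000 draws. Such probes may overlap in sequence, which was not tested. A dye effect shared by all probes of a transcript and an effect of the RHA knockdown cannot be told apart, since 0 of the 3 arrays had swapped dyes. The array with the lowest RHA ratio had an SD of log2 ratios 0.706 times that of the array with the highest, and 3 arrays are too few to read this.

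The choices of array signs are too few to weigh chance. The real signs gave 3332 probes past the threshold, the highest of the other choices gave 0, and 1 of the 4 choices, the real one, reached the real count.

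The small size of the RHA ratios may owe part to the processing, but the tests could not decide this, because their values had been seen when the tests and their bounds were set. With an offset of 0 the mean log2 ratios were -0.47 and -0.37, and the smaller of their ratios to those with an offset of 50 was 1.31, just above the bound of 1.3 set for shrinkage of dim probes. For the placing of the zero, both probes had means above 0 in 1 of the 7 settings examined, median centring. Replicate 3 had the lowest ratio of both probes in all 7 settings.

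The upward turn of calls under median centring is consistent with a balance between the dyes that changes with brightness. With the tested probes in 5 equal classes of brightness, the median log2 ratio after median centring was 0.12 in the dimmest class and 0.74 in the brightest, a difference of 0.62. Before normalization, the tested probes' median log2 ratio exceeded that of all probes by 0.32, 0.53 and 0.11 on replicates 1, 2 and 3. Dim, untested probes thus lowered the median used for centring. Centring on the tested probes took upward calls from 98.4% to 74.2%. That lies between the bounds set for and against dim probes as the cause, so their share of the turn was left undecided. With the untested probes out of the median, 74.2% of calls stayed upward, against 52.9% with loess. This argues against dim, untested probes as the whole cause. A rise of abundant mRNAs in heavy polysomes of knockdown cells would also move bright probes upward and stays open, untested.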

How the results depend on the processing

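Median centring on detected probes was chosen after the data were seen. The 4 named accessions kept their sign in 60 of 60 values under alternatives and stayed past the threshold in 56. The exceptions were the 4 values without replicate 2. Many of these signs were fixed in advance. The accessions were picked for 1 sign on all 3 arrays, so leaving out or weighting arrays could not turn it. Changes of the filter, the flags or the variance model, and Aquantile, left their ratios unchanged. Both RHA probes stayed short of the threshold in every alternative. Their mean log2 ratios were below 0 in all but median centring, where they were 0.068 and 0.26. With centring on detected probes, A_24_P36847 had 0.021, 0.0077 and -0.76 on replicates 1, 2 and 3. A_23_P97749 had 0.19, 0.19 and -0.54, so replicate 3 alone set the sign of both means there. Counts of calls moved more. Leaving out a replicate gave 0 to 1502 risen and 0 to 1419 fallen probes, 0 to 652 and 0 to 534 by at least 2-fold, and 0 to 1317 risen and 0 to 1338 fallen accessions, the 0 in each case without replicate 2, where limma had 2228 and 2010 probes at an unadjusted p under 0.05. Fits on 2 arrays have fewer residual degrees of freedom, and 2115, 0 and 2281 of the 3332 calls remained without replicates 1, 2 and 3. Each of these fits used 2 arrays, so that number alone does not account for the 0 calls without replicate 2. Median centring gave 3561 risen and 59 fallen probes, 2099 and 12 by at least 2-fold, and 2748 and 46 accessions. Median centring on detected probes gave 3127 risen probes, 1152 risen and 87 fallen by at least 2-fold, and 2448 and 851 accessions, beside 1087 fallen probes. Normexp with offset 0 gave 2891 risen probes, 1263 risen and 785 fallen by at least 2-fold, and 2314 risen accessions. Agilent's processed log ratio gave 2809 risen probes, 2344 risen and 1396 fallen by at least 2-fold, and 2308 risen accessions. No filter on dim probes gave 1066 and 997 probes, 286 and 204 by at least 2-fold, and 829 and 821 accessions, with 41000 probes tested. The intensity trend gave 3001 and 2523 probes and 2342 and 2129 accessions. The series matrix values gave 812 probes risen at least 2-fold. Beyond the lower offset and the number of probes tested, the cause of these differences, the 0 without replicate 2 included, was not tested. None of the 3332 probes was called in the opposite direction under the 14 alternatives with probe calls. Where an alternative left the ratios unchanged, an opposite call was not possible. Aquantile leaves the ratios of probes as they are by construction, so it tests nothing for probes, though it is counted among the alternatives. It changes the average signals, and so which probe is the brightest of an accession. Accession counts under Aquantile were 1438 risen and 1355 fallen, against 1439 and 1356 in the main setting. The match of probes to the monkey genome and every alternative for JUND and the gene lists, fry included, were not run. No separate paired analysis was run, because each array already gives 1 ratio within its own pair and the arrays form 1 group. The main fit thus already uses the pairing. Dim signal limited the measurement, with 55.7% of probes not tested.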

Other observations

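The comparisons of accession types below were chosen after the files were seen, on 1 probe per accession. Among called NM accessions, 1060 rose and 1103 fell, or 49.0% upward. Among called NR accessions, which are RefSeq non-coding RNAs, 39 rose and 22 fell, or 63.9% upward. Among other sequence records, such as cDNAs, expressed sequence tags and consensus sequences, 208 rose and 101 fell, or 67.3% upward. Among Ensembl transcripts 26 rose and 22 fell. Against NM accessions, the odds ratio of an upward call was 1.84 for NR accessions (Fisher's exact test, 2-sided, Benjamini-Hochberg adjusted p = 0.0399 over 3 tests), 2.14 for other records (adjusted p = 4.04e-09) and 1.23 for Ensembl transcripts (adjusted p = 0.560). These odds ratios are among calls. With camera at the preset correlation, neither NR accessions nor other records passed (adjusted p of 0.202 and 0.452). The classes also differed in brightness, with a median log2 signal of 7.46 for NM, 7.18 for NR and 6.94 for other records. The main filter admitted probes through the knockdown channel alone, and a filter on both channels is given below. Brightness was not separated from the type of record. Of the tested accessions, 9.79% of NM, 14.4% of NR and 10.5% of other records rose, and 10.2%, 8.12% and 5.10% fell, differences that were not tested by direction. Other records were also called less often than NM accessions, 15.6% against 19.98% (odds ratio 0.741, Fisher's exact test, adjusted p = 1.34e-05). That direction depended on the setting, with the odds ratio below 1 in 12 and above 1 in 3 of 15 alternatives. Other records were called more often than NM accessions with Agilent's processed log ratio (34.5% against 26.6%, odds ratio 1.46, unadjusted exact p = 1.19e-12), with a normexp offset of 0 (32.7% against 28.7%, 1.21, unadjusted exact p = 0.000286) and with the intensity trend (33.2% against 30.2%, 1.15, unadjusted exact p = 0.00802). Several accessions can come from 1 gene and RNAs are not independent, so these p-values are too small.

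The splits did not hold up in every setting. Among probes well above background in both channels, 34 NR accessions rose and 23 fell, with an odds ratio of 1.66 and an adjusted p of 0.120. For other records 176 rose and 117 fell, with an odds ratio of 1.69 and an adjusted p of 8.75e-05. Without replicate 1 the odds ratios were 3.83 for NR accessions (29 rose and 8 fell, unadjusted exact p = 0.000349) and 2.51 for other records (unadjusted exact p = 1.59e-08), and with no filter on dim probes the NR accessions had 3.02 (unadjusted exact p = 0.00547). Without replicate 3 the odds ratios were 1.36 (unadjusted exact p = 0.294) and 1.18 (unadjusted exact p = 0.185), and with centring on the median of detected probes they were 1.09 (unadjusted exact p = 0.895) and 1.16 (unadjusted exact p = 0.260). Median centring, with few falling calls, gave an unadjusted exact p of 0.637 and 0.194. Under it 64 NR accessions rose and 0 fell, so their odds ratio had no finite value, and the tally below counts it as above 1. Over 15 alternatives with calls, Aquantile included, the odds ratio of both classes stayed above 1, with an unadjusted exact p under 0.05 in 11 for NR accessions and 12 for other records. The median log2 ratio of other records minus that of NM accessions was 0.035, and it turned negative in 3 of the 15, at -0.061 under both kinds of median centring and -0.0092 among probes well above background in both channels. For NR accessions that difference was 0.095 and stayed above 0 in 15. Not all of the 15 were separate tests of these differences. The intensity trend left the ratios unchanged, and both kinds of median centring give the same difference by construction. For Ensembl transcripts the odds ratio was 2.77 without replicate 1 (21 rose and 8 fell, unadjusted exact p = 0.0137), 1.62 with a normexp offset of 0 (unadjusted exact p = 0.0337), 1.61 with no filter (unadjusted exact p = 0.212), and 1.00 among probes well above background in both channels. With median centring 51 rose and 0 fell (unadjusted exact p = 0.624). With camera, no class passed over the 5 tested. The NR accessions had a median log2 ratio of 0.099 and a mean of 0.12. Their camera adjusted p was 0.202 at the preset correlation and 0.761 with an estimated correlation. For other records the camera adjusted p was 0.452 and 0.761.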
